A study of Arabidopsis thaliana with 12 samples.

How the data were processed

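Messenger RNA from Arabidopsis thaliana leaves was sequenced in 12 libraries, 3 from each of 4 genotypes: the Columbia wild type (WT), the double mutant crwn1;4, and the double mutant combined with either pnet2_a or pnet2_b. These last genotypes are called the pnet2_a triple mutant and the pnet2_b triple mutant here, and crwn1;4 the double mutant. Per the labels' protocols, about 50 mg of leaf went into each RNA preparation and the libraries were strand-specific and read on a HiSeq 2000. The titles and sample characteristics give a plant age of 3 weeks and the protocol gives 4 weeks, so the age is known only as either of these. Genotype and replicate number were taken from the sample titles. Nothing in the labels says that replicates came from separately grown plants, so p-values measure the spread between these samples, which may be technical.

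The deposited table holds 1 FPKM value per gene and library, made by the authors and named as FPKM in the table itself. FPKM is the number of sequenced fragments of a gene divided by the gene's length and by the mapped fragments of the library. Per the submitters' processing notes, HISAT2 version 2.0.4 and the TAIR10 genome were used. The program that counted the fragments, the gene annotation release and the strand setting are not given in the sources used here. FPKM removes depth from the values, and low values were checked for fixed steps that would give the worth of 1 read. For genes below 0.8 FPKM in both libraries of a pair (749 to 955 genes), the ratios between libraries were sorted into 0.01-wide log2 steps. Over the 12 pairs of libraries of the same genotype no step held more than 1.79% of the ratios, so none stood out and the depth of the libraries is unknown. The smallest values above 0 were 0.293 to 0.336 FPKM, depending on the library. A gene at exactly 0 is therefore described as listed at 0, with no fold change against it. The library totals were 622263 to 669711 FPKM, and no library was scaled further for the values reported first.

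Of 32833 genes in the table, 32548 matched a locus of the TAIR10.1 reference annotation, from which symbols and coordinates were taken. The 285 others all carry a mitochondrial or plastid prefix. Genes with at least 1 FPKM in at least 3 of the 12 libraries were kept, which left 19110. Differences were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with genotype as the only term, empirical Bayes moderation with an intensity trend, and 1 fit over all 12 libraries (8 residual degrees of freedom). A log2 change is therefore on the log2(FPKM + 1) scale, which understates changes of genes with low values. P-values were adjusted by the Benjamini-Hochberg method over the genes kept within each of 6 comparisons, and a gene rose or fell where its adjusted p was below 0.05. Mean ± SD values are of FPKM over 3 libraries, and SE is the standard error of the log2 change. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

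Gene lists for 40 pathways, responses and cell types were written before the data were examined, and so were the design, the rule for the genes named and the alternative settings. Of 573 list entries, 546 had the listed name at their locus in the reference, and the other 27 were used by locus. A list was tested with limma's camera (preset inter-gene correlation of 0.01) where at least 5 members were kept, which held for 37 lists, and p-values were adjusted over lists and all 6 comparisons. The tests were run again with the correlation estimated from the data. Camera sets the members of a list against all other genes. Where a list's median change is given relative to all genes, the median of all genes kept was subtracted. In the first 3 comparisons described, members were also counted with the adjustment made over the list alone, and where no such count is printed it equals the count over all genes.

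The genes named are CRWN1 and CRWN4 first. In each of the first 3 comparisons described, they also include the 10 largest rises and the 10 largest falls among genes past the threshold with a higher genotype mean of at least 5 FPKM and no overlap between the libraries, at most 2 in each direction without a symbol. Up to 4 members of each list with the smallest adjusted p are added. For the other 3 comparisons, the 3 largest rises and falls and genes already named were taken. The text names part of these, and genes outside the rule are said to be chosen after their values were seen. The alternatives were pseudocounts of 0.1 and 5, no filter and a filter of 5 FPKM, rescaling to a common total (TPM), median-ratio scaling, quantile normalization, limma without the trend, array weights, a fit on the 2 genotypes compared, replicate number as a block, a 2-fold minimum, fry in place of camera, and each library left out in turn.

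To follow the genes of the double mutant into the triple mutants without using a library for both selection and measurement, each double mutant library was held out in turn. Genes were called with the libraries that remained, and the change in the triple mutants was measured against the library held out. The chance level of the similarity between the triple mutants, which share their double mutant controls, was taken from 100 simulations of unchanged genotypes. The test was checked on simulated data with 19110 genes, of which 200 that were not low were changed, and the photosystem list was shifted besides. The noise was independent between genes and of equal spread in every genotype. Far fewer genes changed there than in the triple mutants, so the rates need not hold for low genes or for the real comparisons. Across the 6 comparisons, 50 to 68% of genes changed by a log2 of 0.5, 94 to 100% of those changed by 1 and 96 to 100% of those changed by -1 were recovered, and 4.3 to 9% of the calls were unchanged genes.

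Near-identical genes, such as those of the LHCB1 and RBCS families, share reads, and overlapping or antisense genes cannot be separated without the strand setting, so single members of such pairs are uncertain. The PNET2 genes are not reported here, since no locus of the reference used carries that name.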

Results

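Leaf transcripts were measured in 4 Arabidopsis genotypes with 3 libraries each, as FPKM per gene. CRWN1 and CRWN4 encode coiled-coil proteins of the plant nuclear lamina, and the PNET2 proteins are membrane proteins of the nuclear envelope. The series asks what loss of PNET2_A or PNET2_B adds to the loss of both CRWN proteins in crwn1;4, the double mutant. Between 19841 and 21022 genes had values above 0 in a library, and the read depth is unknown. Across genes, which are not independent replicates, the correlation of log2 values was 0.9843 to 0.9885 between libraries of 1 genotype and 0.9243 to 0.9844 between libraries of different genotypes. The first principal component held 65% of the variance and placed WT at -45.9 ± 0.839, the double mutant at -29.5 ± 7.81, the pnet2_a triple mutant at 31.4 ± 2.40 and the pnet2_b triple mutant at 44.1 ± 2.94 (mean ± SD, n = 3 each). Replicate 3 of the double mutant lay at -20.8, nearer to the triple mutants than the other double mutant libraries at -35.9 and -31.9.

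The composition of the libraries also differed with genotype. Members of the photosynthesis lists made up 27.6 ± 0.715% of all FPKM in WT and 27.9 ± 0.916% in the double mutant, but 22.9 ± 0.598% in the pnet2_a and 18.6 ± 0.5% in the pnet2_b triple mutant. Since FPKM values are shares of a library, the lower share of these abundant transcripts went with higher values elsewhere. The median log2 change of all genes was 0.11 in the pnet2_a and 0.23 in the pnet2_b triple mutant against the double mutant, and 0.01 in the double mutant against WT. List changes are therefore also given relative to the median of all genes. Plastid-encoded transcripts totalled 743 ± 33.9 FPKM in WT, 658 ± 62.7 in the double mutant, 460 ± 5.8 in the pnet2_a and 486.2 ± 78.1 in the pnet2_b triple mutant. The capture of such transcripts by mRNA libraries varies with RNA preparation. Mitochondrial transcripts totalled 56.5 ± 5.89, 51.5 ± 0.764, 52.3 ± 0.833 and 56.7 ± 3.3 FPKM in the same order. Lists for flower organs, seeds and roots had too few members kept for a test. Their highest values in any single library were 2.96 FPKM for SEP1, 0.691 for CRU1 and 10.5 for SCR.

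Both targeted CRWN genes were low in every mutant library. CRWN1 (AT1G67230, chromosome 1, 25151211 to 25156389 in TAIR10.1) had 12.4 ± 0.949 FPKM in WT, 1.87 ± 0.129 in the double mutant, 1.67 ± 0.208 in the pnet2_a and 1.75 ± 0.265 in the pnet2_b triple mutant (mean ± SD, n = 3). The mutants held 15.0%, 13.4% and 14.1% of the WT level. CRWN4 (AT5G65770, chromosome 5, 26311311 to 26316025) had 7.36 ± 0.967 FPKM in WT, 1.26 ± 0.0341 in the double mutant, 1.56 ± 0.0794 in the pnet2_a and 1.51 ± 0.5 in the pnet2_b triple mutant, so the double mutant held 17.1% of the WT level. CRWN4 overlaps AT5G65780, so its values may hold reads of that gene. In the double mutant against WT the log2 change was -2.23 for CRWN1 (SE 0.124, limma adjusted p = 1.2e-07) and -1.88 for CRWN4 (SE 0.151, adjusted p = 1.13e-05). Neither gene differed past the threshold between a triple mutant and the double mutant, with adjusted p of 0.558 and 0.395 in the pnet2_a and 0.694 and 0.484 in the pnet2_b triple mutant. Quantile normalization alone among the alternatives called 1 of these, CRWN1 in the pnet2_b triple mutant (log2 change -0.36, adjusted p = 0.0217).

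**Figure D1:**
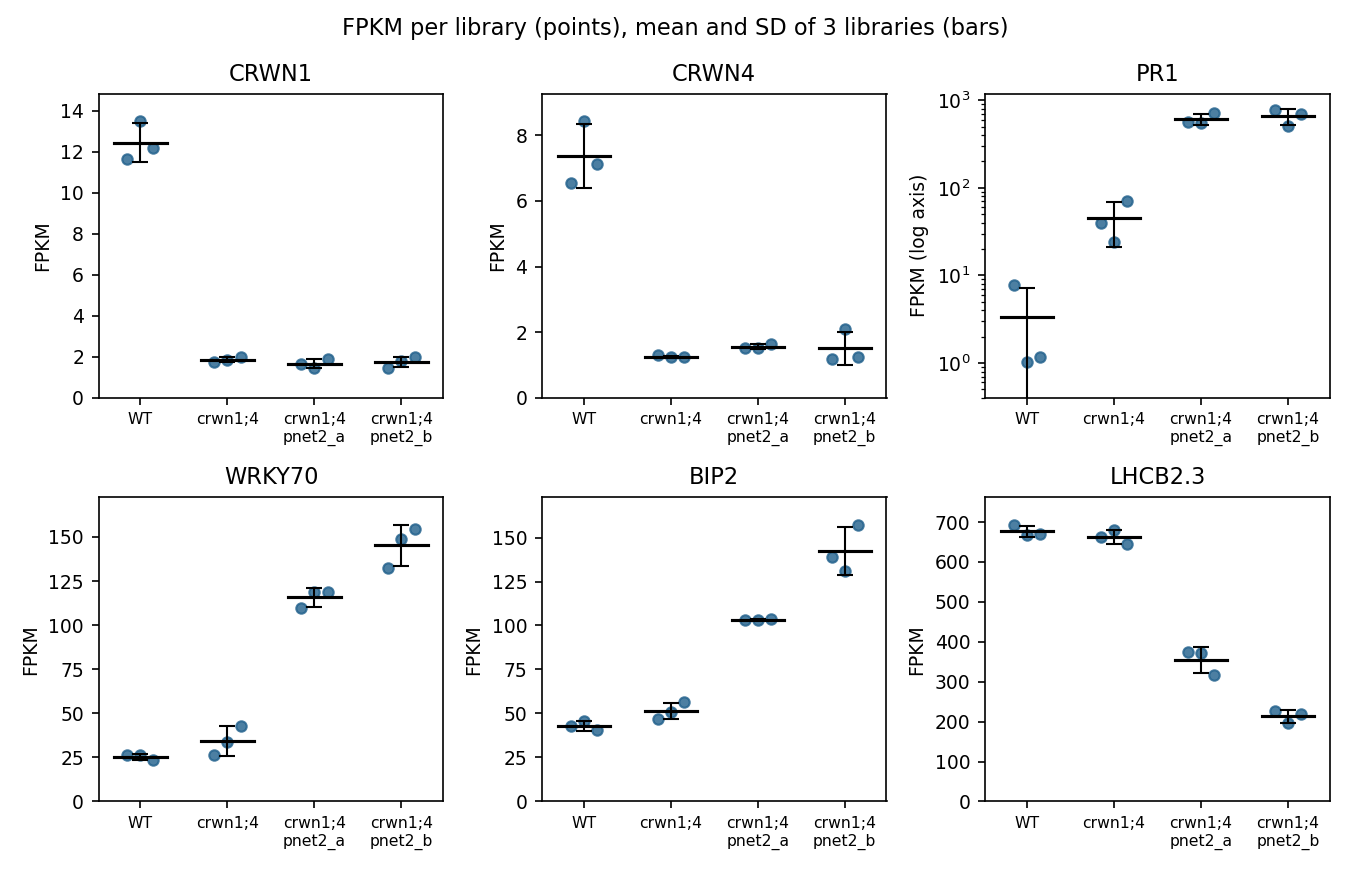
FPKM per library in the 4 genotypes for CRWN1, CRWN4, PR1, WRKY70, BIP2 and LHCB2.3, with points for libraries and bars for the mean and SD of 3 libraries. The PR1 axis is logarithmic and the lower SD bar of WT runs below it, since the SD of 3.87 exceeds the mean of 3.33. PR1 lies between 512 and 772 FPKM in the triple mutant libraries, above every library of the double mutant and WT.

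The comparison of the double mutant with WT addresses the loss of CRWN1 and CRWN4. Marker transcripts of salicylic acid defence were higher in the double mutant. PR1, the usual marker of salicylic acid signalling, had 44.7 ± 23.4 FPKM in the double mutant and 3.33 ± 3.87 in WT (mean ± SD, n = 3 each), a log2 change of 3.63 (SE 0.453, adjusted p = 0.000505). PR2, a beta-1,3-glucanase induced with it, had 35.0 ± 24.9 against 3.78 ± 0.501 FPKM (log2 change 2.71, SE 0.318, adjusted p = 0.000329), and PR5 had 41.9 ± 17.8 against 11.2 ± 1.13 (log2 change 1.74, SE 0.202, adjusted p = 0.000301). PR1 stood at 39.5, 24.3 and 70.3 FPKM in the double mutant libraries, the highest in replicate 3, and at 7.80, 1.02 and 1.17 in WT.

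In all, 574 of 19110 genes changed, 461 of them upward and 113 downward, which is 3.0% of the genes tested. Changes of at least 2-fold were 106 rises and 11 falls. The libraries of the genotypes did not overlap at 19.8% of genes, where chance gives 10%. The largest rises also held AED1 (log2 change 1.91), PCR1 (2.1), CRK6 (1.91) and the chitinase CHI (2.16), whose mean rose from 0.555 ± 0.600 to 6.39 ± 4.52 FPKM. The microRNA locus MIR5642a had 11.8 ± 2.02 FPKM in the double mutant and 1.64 ± 0.144 in WT (log2 change 2.26, adjusted p = 6.53e-08). It overlaps AT3G41762 and AT3G06325, so its reads may be theirs, and a rise of the microRNA itself is not shown. Among the falls were FTM1, with 4.38 ± 1.08 against 10.2 ± 2.48 FPKM (log2 change -1.06, SE 0.193, adjusted p = 0.00813), MUB2 (log2 change -0.70) and AT1G06957 (log2 change -1.98).

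Of the 17 genes listed for pathogenesis-related proteins and systemic acquired resistance, 7 rose and none fell, or 8 adjusted over the list alone, and the list was called upward (camera adjusted p = 6.25e-09, adjusted p = 0.149 with an estimated correlation). Of 18 genes of salicylic acid synthesis and signalling, 5 rose and 13 did not pass, or 11 rose adjusted over the list alone (adjusted p = 1.66e-07, adjusted p = 0.152 with an estimated correlation). They included CBP60G, an activator of salicylic acid synthesis (5.42 ± 1.06 against 1.71 ± 0.105 FPKM, log2 change 1.23), and WRKY38 (log2 change 1.31). Of 9 genes of camalexin synthesis, the main indolic phytoalexin of Arabidopsis, 4 rose, and 8 did adjusted over the list alone (adjusted p = 3.89e-07, adjusted p = 0.0871 with an estimated correlation). GSTF6 had 39.6 ± 10.7 against 16.4 ± 1.47 FPKM and PAD3 1.98 ± 0.656 against 0.628 ± 0.0979. Of 20 NLR immune receptors 1 rose, or 10 adjusted over the list alone, and of 14 genes of pattern-triggered immunity 1 rose, or 3 with 1 fall adjusted over the list alone. Both lists were called upward (adjusted p = 3.11e-05 and 0.00227, with adjusted p = 0.224 and 0.115 with an estimated correlation).

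Lists for cold, water deficit and oxidative stress were called in the same direction, each with part of its members passing. Of 13 cold response genes 4 rose, or 10 adjusted over the list alone (median relative to all genes 0.49, adjusted p = 6.18e-10, adjusted p = 0.073 with an estimated correlation). COR15A, a chloroplast cryoprotective protein, had 60.1 ± 7.0 against 34.9 ± 2.15 FPKM (log2 change 0.77, SE 0.083, adjusted p = 0.000173), and COR47 had 103.5 ± 6.40 against 73.2 ± 5.29. Of 12 genes of abscisic acid and drought response 4 rose, or 9 adjusted over the list alone (adjusted p = 7.43e-08, adjusted p = 0.112 with an estimated correlation), among them RD29A (61.5 ± 8.74 against 36.3 ± 4.17 FPKM). Of 10 oxidative stress genes 5 rose, or 7 adjusted over the list alone, and this list alone was still called with an estimated correlation (adjusted p = 1.73e-09, adjusted p = 0.0318 with an estimated correlation). ZAT12 and ZAT10, zinc finger regulators of stress responses, had log2 changes of 1.08 and 1.43, and the mitochondrial alternative oxidase AOX1A had 25.4 ± 2.11 against 15.6 ± 0.392 FPKM.

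Other lists were called upward with fewer members passing singly: leaf senescence with 4 of 17 genes past the threshold (SAG21 26.4 ± 8.36 against 10.8 ± 2.06 FPKM), endoplasmic reticulum folding with 2 of 14 (CRT3 40.1 ± 8.13 against 25.5 ± 2.85 FPKM, BZIP60 23.59 ± 1.11 against 16.3 ± 1.85), cell expansion with 2 of 11 (TCH4 29.4 ± 7.38 against 15.3 ± 1.15), indole glucosinolate synthesis with 2 of 11, energy starvation with 1 of 12, jasmonate with 1 of 21 and morning clock genes with 0 of 11 (7 at an unadjusted p below 0.05). Adjusted over the list alone these were 8, 4, 4, 4, 3, 5 and 6 genes. Their adjusted p were 4.6e-06, 0.000158, 0.00165, 0.0028, 0.00342, 0.0113 and 0.000285, and with an estimated correlation the adjusted p were 0.132, 0.348, 0.247, 0.166, 0.22, 0.393 and 0.073. The jasmonate call ended without WT replicate 2 (adjusted p = 0.192) or double mutant replicate 2 (0.208), and the indole glucosinolate call without double mutant replicate 2 (0.0504). The rotation test fry, which does not set a list against other genes, did not call jasmonate (adjusted p = 0.0939) or endoplasmic reticulum folding (0.0704).

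Other lists were called downward, though few members passed singly. Of 13 guard cell and stomatal lineage markers 1 fell, or 3 adjusted over the list alone, with a median of -0.27 relative to all genes (adjusted p = 0.000287, adjusted p = 0.14 with an estimated correlation). The member that fell was FAMA, a regulator of guard cell fate, at 7.02 ± 0.206 against 10.2 ± 0.341 FPKM (adjusted p = 0.0177), whose call ended without WT replicate 1 (0.0553) or 3 (0.0599) and without double mutant replicate 1 (0.0583) or 3 (0.0566). Its adjusted p over all alternatives was 0.0136 to 0.0766. None of 21 genes of cell cycle and DNA replication, of 18 of aliphatic glucosinolate synthesis and of 12 vascular markers passed limma's test, also adjusted over the list alone, though 5, 4 and 2 fell at an unadjusted p below 0.05. Their list medians relative to all genes were -0.19, -0.08 and -0.21 (adjusted p = 0.000156, 0.0115 and 0.0143). With an estimated correlation their adjusted p were 0.22, 0.548 and 0.373. The aliphatic call ended without double mutant replicate 1 (adjusted p = 0.249) or 3 (0.179), and the vascular call without WT replicate 2 (0.159) or double mutant replicate 1 (0.0627) or 3 (0.0688). Fry called neither of these lists (adjusted p = 0.381 and 0.166).

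Photosynthesis lists were not called in the double mutant with all libraries and the deposited FPKM. None of 18 light-harvesting antenna genes and none of 22 photosystem subunits passed (list adjusted p = 0.218 and 0.0901), though 1 antenna gene fell adjusted over the list alone and 1 gene of each list fell at an unadjusted p below 0.05. Of 16 carbon fixation genes 2 fell, or 3 with 1 rise adjusted over the list alone (adjusted p = 0.764). Of 14 chlorophyll synthesis genes 1 rose, or 5 adjusted over the list alone (adjusted p = 0.0748). Single libraries gave calls in opposite directions. The antenna list was called upward without WT replicate 1 (adjusted p = 0.0169) or double mutant replicate 3 (0.0468), and the photosystem list downward without WT replicate 2 (0.0171) or double mutant replicate 1 (0.0121). Carbon fixation was called downward without double mutant replicate 1 (0.0384). Chlorophyll synthesis was called upward under quantile normalization (0.00417), with no filter (0.0469), without WT replicate 1 (0.00976) and without double mutant replicate 2 (0.0231) or 3 (0.0207). Among 15 genes of the DNA damage response 1 rose, SMR7 (1.57 ± 0.0635 against 0.222 ± 0.384 FPKM), and none of 21 genes of the nuclear lamina and nuclear envelope passed, where 1 fell at an unadjusted p below 0.05 (list adjusted p = 0.794 and 0.82). The camera adjusted p of the remaining lists were 0.467 for jasmonate-ethylene defence, 0.168 for ethylene, 0.55 for auxin, 0.38 for heat shock, 0.132 for copper, 0.214 for iron deficiency, 0.856 for phosphate, 0.23 for flavonoids, 0.78 for evening clock genes, 0.447 for DNA methylation, 0.964 for flowering time and 0.408 for epidermis markers. Among these lists, 1 of 5 ethylene genes, 1 of 12 heat shock genes and 1 of 8 epidermis markers rose (with 1 fall adjusted over the list alone for epidermis), and of 14 flavonoid genes 1 rose and 1 fell. None passed limma's test in the others, where 1 copper gene fell and 1 iron gene rose and 1 fell adjusted over the list alone. At an unadjusted p below 0.05, 1 gene rose and 3 fell for copper, 1 rose and 1 fell each for iron and jasmonate-ethylene defence, 3 auxin genes rose, 1 phosphate and 1 flowering time gene rose, and none changed for evening clock and DNA methylation. The copper list was called downward with a filter of 5 FPKM (adjusted p = 0.0443) and without double mutant replicate 2 (0.0372), and so was the flavonoid list without that library (0.00765). Many single-gene calls here rested on the spread pooled over all 4 genotypes and on single libraries. The fit on these 2 genotypes alone called 29 genes, with PR1 at adjusted p = 0.0754, PR2 at 0.0628 and COR15A at 0.0503. Over the other alternatives the adjusted p was 6.42e-06 to 0.00423 for PR1, 1.78e-05 to 0.00341 for PR2 and 5.57e-05 to 0.00226 for COR15A. In it, 53 of the 62 genes named by rule lost their call. The count was 377 without WT replicate 3 and 301 without double mutant replicate 3. Of the 62 named genes, 25 lost their call when some library was left out, 23 of them without double mutant replicate 3.

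The comparison of the pnet2_a triple mutant with the double mutant addresses what pnet2_a adds. The pnet2_a mutation itself was not checked in these libraries, so the differences are those between lines labelled with and without it. All 17 pathogenesis-related and 17 of 18 salicylic acid genes rose above the level of the double mutant, while all 22 photosystem subunits and 17 of 18 antenna genes fell. None of these list calls was kept with an estimated correlation (adjusted p = 0.115, 0.0936, 0.073 and 0.14 with an estimated correlation). PR1 had 608.6 ± 89.6 FPKM in the triple mutant and 44.7 ± 23.4 in the double mutant (mean ± SD, n = 3 each; log2 change 3.86, SE 0.453, adjusted p = 2.03e-05), and PR2 had 238.3 ± 50.8 against 35.0 ± 24.9. ARD3 (38.4 ± 3.48 against 1.89 ± 0.749 FPKM, log2 change 3.80), the glucanase gene BG3 (47.5 ± 6.50 against 3.44 ± 2.11, 3.55) and SAG13 (48.6 ± 7.20 against 4.37 ± 2.54, 3.3) were the next largest rises under the rule with a symbol. The falls included SEN1 (3.1 ± 0.575 against 19.9 ± 1.62 FPKM, log2 change -2.36), GASA6 (85.5 ± 3.12 against 233.2 ± 21.3, -1.43) and the vegetative storage protein gene VSP1 (2.81 ± 0.999 against 17.7 ± 6.84, -2.25).

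With the deposited FPKM, 6139 of 19110 genes changed (32.1%), 4380 upward and 1759 downward, so 71.3% were rises. Median-ratio scaling gave 5747 genes with 2975 rises and 2772 falls (51.8% rises), and quantile normalization gave 2666 rises and 3086 falls (46.3%). The balance of rises and falls depended on the scaling. Changes of at least 2-fold were 818 rises and 121 falls, and 687 and 162 after median-ratio scaling. The libraries did not overlap at 46.9% of genes, where chance gives 10%.

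All 17 listed genes of pathogenesis-related proteins and systemic acquired resistance rose (17 also adjusted over the list alone, median relative to all genes 1.95, camera adjusted p = 7.07e-12, adjusted p = 0.115 with an estimated correlation). Of 18 salicylic acid genes 17 rose, also adjusted over the list alone, with a median of 1.42 (adjusted p = 4.49e-14, adjusted p = 0.0936 with an estimated correlation). WRKY70, a transcription factor of this pathway, had 115.7 ± 5.19 against 34.2 ± 8.50 FPKM (log2 change 1.76, SE 0.129, adjusted p = 4.13e-07), and the salicylate hydroxylase gene DMR6 had 110.9 ± 12.8 against 18.9 ± 6.96. Of 9 camalexin genes 8 rose (adjusted p = 6.1e-06, adjusted p = 0.0936 with an estimated correlation), with PAD3 at 18.9 ± 3.28 against 1.98 ± 0.656 FPKM. Of 20 NLR receptors 15 rose, or 16 adjusted over the list alone (adjusted p = 2.83e-06, adjusted p = 0.185 with an estimated correlation), among them ZAR1 (65.6 ± 1.99 against 30.8 ± 2.43 FPKM) and ADR1 (7.71 ± 0.189 against 3.05 ± 0.336). Of 14 genes of pattern-triggered immunity 9 rose, with 1 fall adjusted over the list alone (adjusted p = 0.00961, adjusted p = 0.149 with an estimated correlation), such as FRK1 at 6.0 ± 1.23 against 1.01 ± 0.585 FPKM.

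Genes of protein folding in the endoplasmic reticulum rose as a whole list. All 14 passed, also adjusted over the list alone, with a median of 0.81 relative to all genes (adjusted p = 1.51e-10, adjusted p = 0.152 with an estimated correlation). The chaperone gene BIP2 had 103.3 ± 0.328 against 51.4 ± 4.66 FPKM (log2 change 1.00, SE 0.079, adjusted p = 7.77e-07). BIP2 shares reads with its near copy BIP1. CRT3 had 121.2 ± 8.83 against 40.1 ± 8.13 FPKM. Of 15 DNA damage genes 10 rose, or 11 adjusted over the list alone (adjusted p = 0.000449, adjusted p = 0.162 with an estimated correlation), with PARP2 at 7.32 ± 0.647 against 2.66 ± 0.419 FPKM and GMI1 at 4.04 ± 0.5 against 1.09 ± 0.334. Of 17 leaf senescence genes 15 rose and 1 fell (adjusted p = 1.27e-05, adjusted p = 0.143 with an estimated correlation), with WRKY53 at 24.4 ± 3.80 against 4.34 ± 1.26 FPKM. The lists for indole glucosinolates (8 of 11 rose, 1 fell), evening clock genes (6 of 9 rose, or 7 adjusted over the list alone), iron deficiency (5 of 8 rose) and phosphate starvation (6 of 10 rose) were also called upward, with adjusted p = 0.00283, 0.0025, 0.00801 and 0.0289. With an estimated correlation their adjusted p were 0.166, 0.303, 0.197 and 0.188. The phosphate call ended without replicate 1 (adjusted p = 0.105) or 3 (0.0665) of this triple mutant and without double mutant replicate 3 (0.0626), and with a pseudocount of 0.1 (0.06). The iron call ended with no filter (0.0822).

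All 22 photosystem subunits fell, also adjusted over the list alone, with a median of -0.43 relative to all genes (adjusted p = 3.86e-20, adjusted p = 0.073 with an estimated correlation). Of 18 light-harvesting antenna genes 17 fell (median -0.49, adjusted p = 2.69e-16, adjusted p = 0.14 with an estimated correlation). LHCB2.3 had 353.7 ± 32.7 against 662.5 ± 16.8 FPKM (log2 change -0.91, SE 0.07, adjusted p = 5.47e-07), and PSAD2 had 926.9 ± 53.4 against 1267 ± 5.72. Of 14 chlorophyll synthesis genes 9 fell, or 10 adjusted over the list alone (adjusted p = 2.61e-08, adjusted p = 0.149 with an estimated correlation), among them HEMA1, of the first committed step (130.9 ± 8.25 against 197.2 ± 6.39 FPKM). Of 16 carbon fixation genes 9 fell (adjusted p = 4.21e-06, adjusted p = 0.315 with an estimated correlation). Quantile normalization, which sets the highest values of all libraries equal, ended the antenna (adjusted p = 0.386, median change 0) and carbon fixation (0.633) calls. The photosystem list kept a median of -0.11 under it (adjusted p = 0.00662), and 5 antenna and 8 photosystem genes still fell.

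Cold, growth and morning clock lists were also called downward, with part of their members falling. Of 13 cold genes 6 fell and 1 rose (adjusted p = 0.00233, adjusted p = 0.188 with an estimated correlation). COR15A had 26.5 ± 1.19 FPKM against 60.1 ± 7.0 in the double mutant and 34.9 ± 2.15 in WT, while ZAT12 rose (log2 change 1.97). The double mutant libraries enter this comparison and that with WT with opposite sign, so a chance deviation in them moves both. Of 12 abscisic acid genes 3 fell and 2 rose (adjusted p = 0.0348, adjusted p = 0.416 with an estimated correlation). Of 11 genes of cell expansion and primary wall 7 fell and 1 rose, or 8 and 1 adjusted over the list alone (adjusted p = 1.12e-05, adjusted p = 0.149 with an estimated correlation), with the expansin EXPA8 at 33.1 ± 7.87 against 67.3 ± 3.54 FPKM. Of 12 energy starvation genes 6 fell and 1 rose. Of 11 morning clock genes 5 fell and 2 rose (CDF1 7.46 ± 0.876 against 18.8 ± 1.55 FPKM). Of 9 auxin response genes 6 fell and 2 rose (3 rose adjusted over the list alone), and of 9 flowering time genes 2 fell. Of 13 guard cell markers 2 fell (KAT1 3.65 ± 0.936 against 8.59 ± 0.511 FPKM), and of 8 epidermis markers 4 fell (CER1 13.3 ± 1.57 against 24.9 ± 4.53 FPKM). These 6 lists had adjusted p = 0.000389, 0.000958, 0.0378, 0.0344, 0.0113 and 0.000691, and with an estimated correlation adjusted p = 0.154, 0.089, 0.203, 0.26, 0.224 and 0.108. The abscisic acid and auxin calls ended without replicate 3 of this triple mutant (adjusted p = 0.0816 and 0.0669), without double mutant replicate 3 (0.0844 and 0.0834) and under quantile normalization (0.0598 and 0.103), the auxin call also under median-ratio scaling (0.0983) and with a pseudocount of 0.1 (0.0501). The abscisic acid call ended with no filter (0.126) and in fry (0.117) as well, and the flowering time call without replicate 1 of this triple mutant (0.0616) or double mutant replicate 3 (0.0718).

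The lists not called were jasmonate (10 rose and 3 fell of 21, or 11 and 3 adjusted over the list alone, adjusted p = 0.0631), heat shock (6 rose of 12, 0.11), oxidative stress (6 rose and 2 fell of 10, or 6 and 3 adjusted over the list alone, 0.159), cell cycle (3 rose of 21, 0.13), copper (4 rose and 1 fell of 10, 0.955), aliphatic glucosinolates (1 rose and 1 fell of 18, 0.0526), flavonoids (1 rose and 1 fell of 14, 0.257), jasmonate-ethylene defence (1 rose of 6, 0.877), ethylene (1 fell of 5, 0.386), DNA methylation (1 rose and 1 fell of 11, and none adjusted over the list alone, 0.81), vascular markers (1 rose and 2 fell of 12, 0.192) and the nuclear lamina and envelope (1 rose and 1 fell of 21, and none adjusted over the list alone, 0.977). Other settings called some of them. Jasmonate was called upward with no filter (adjusted p = 0.0327), median-ratio scaling (0.0481) and quantile normalization (0.0276), and without WT replicate 2 (0.0485), double mutant replicate 2 (0.0166) or replicate 1 (0.0349) or 2 (0.0466) of this triple mutant. Aliphatic glucosinolates were called downward with a filter of 5 FPKM (0.0395), median-ratio scaling (0.0251) and array weights (0.0387), and without double mutant replicate 1 (0.00387) or 3 (0.0121) or replicate 3 of this triple mutant (0.0279). Heat shock was called upward with no filter (0.00853) and median-ratio scaling (0.046), oxidative stress under quantile normalization (0.0301) and cell cycle without replicate 2 of this triple mutant (0.0337). Fry called jasmonate (0.00402), heat shock (0.000431), oxidative stress (8.68e-06), copper (0.0218) and cell cycle (0.0152) upward. Of the 142 genes named by rule, 12 lost their call when some library was left out and 10 under another scaling.

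**Figure D2:**
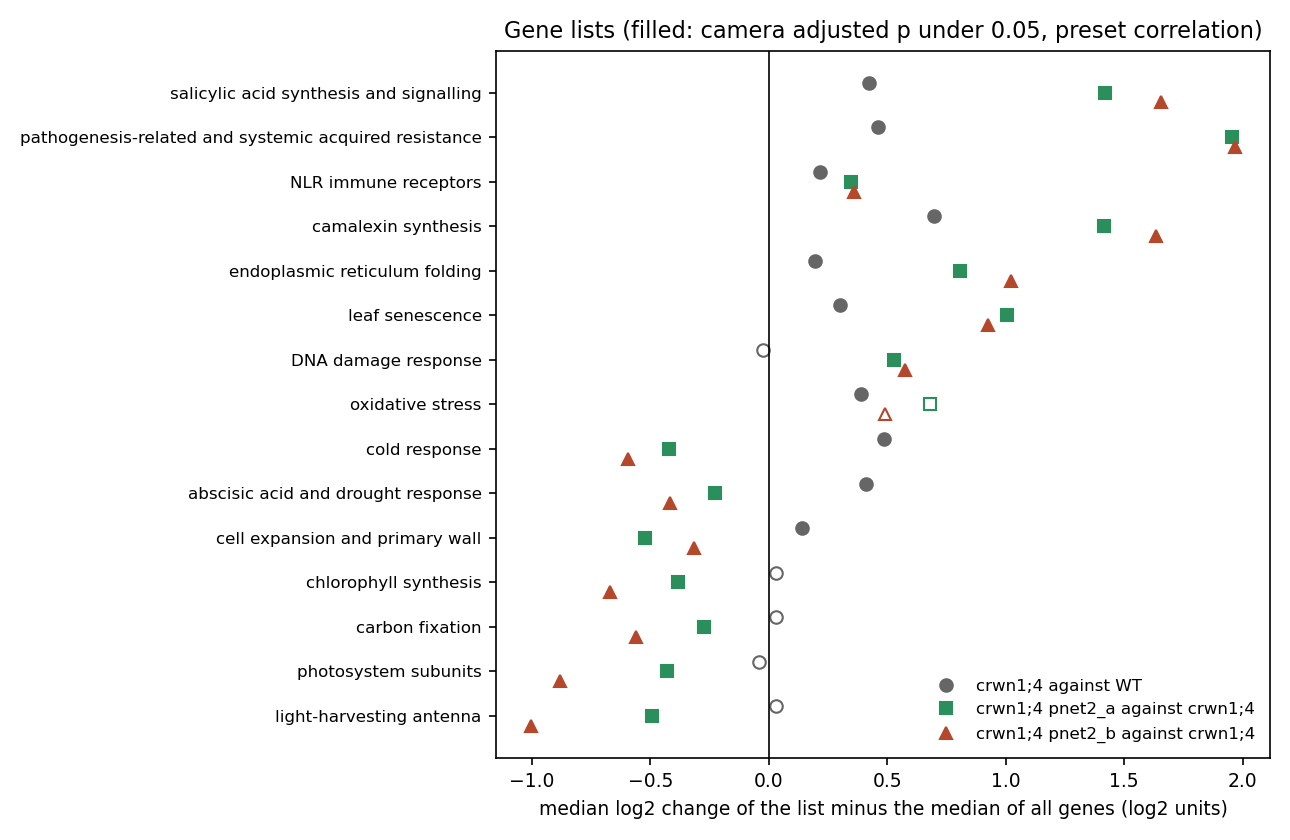
Median log2 change of 15 gene lists minus the median of all genes, in the double mutant against WT and in each triple mutant against the double mutant, with filled points for lists called by camera with the preset correlation (adjusted p below 0.05) and open points for the others. The pathogenesis-related list lies at 0.46, 1.95 and 1.97, and the photosystem list at -0.43 and -0.88 in the triple mutants. Under quantile normalization the antenna median in the pnet2_a triple mutant is 0.

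The comparison of the pnet2_b triple mutant with the double mutant addresses what pnet2_b adds, and the pnet2_b mutation was likewise not checked in these libraries. All 17 pathogenesis-related and all 18 salicylic acid genes rose, while all 22 photosystem subunits and all 18 antenna genes fell. Of these list calls only that of the photosystem list was kept with an estimated correlation (adjusted p = 0.147, 0.108, 0.0321 and 0.089 with an estimated correlation). PR1 had 661.6 ± 134 FPKM against 44.7 ± 23.4 (mean ± SD, n = 3 each; log2 change 3.96, SE 0.453, adjusted p = 9.24e-06), and PR2 had 321.9 ± 60.7 against 35.0 ± 24.9 (log2 change 3.36). Other large rises were CHI (84.5 ± 0.774 against 6.39 ± 4.52 FPKM), the salicylate hydroxylase gene DLO1 (32.8 ± 3.37 against 2.41 ± 1.15), PNP-A (48.7 ± 4.69 against 4.34 ± 3.57) and AT5G52760 (60.7 ± 11.8 against 5.32 ± 3.34). The antenna gene LHCB2.3 fell to 213.6 ± 16.0 from 662.5 ± 16.8 FPKM (log2 change -1.63, SE 0.07, adjusted p = 9.18e-09), and XTH31, of cell wall loosening, to 8.91 ± 1.3 from 25.5 ± 2.69.

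With the deposited FPKM, 9074 genes changed (47.5%), 7424 upward and 1650 downward (81.8% rises). Median-ratio scaling gave 6927 genes with 3498 rises and 3429 falls (50.5% rises), and quantile normalization 3234 rises and 3787 falls (46.1%). Changes of at least 2-fold were 1134 rises and 98 falls, and 807 and 221 after median-ratio scaling. The libraries did not overlap at 57.5% of genes, where chance gives 10%.

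**Figure D3:**
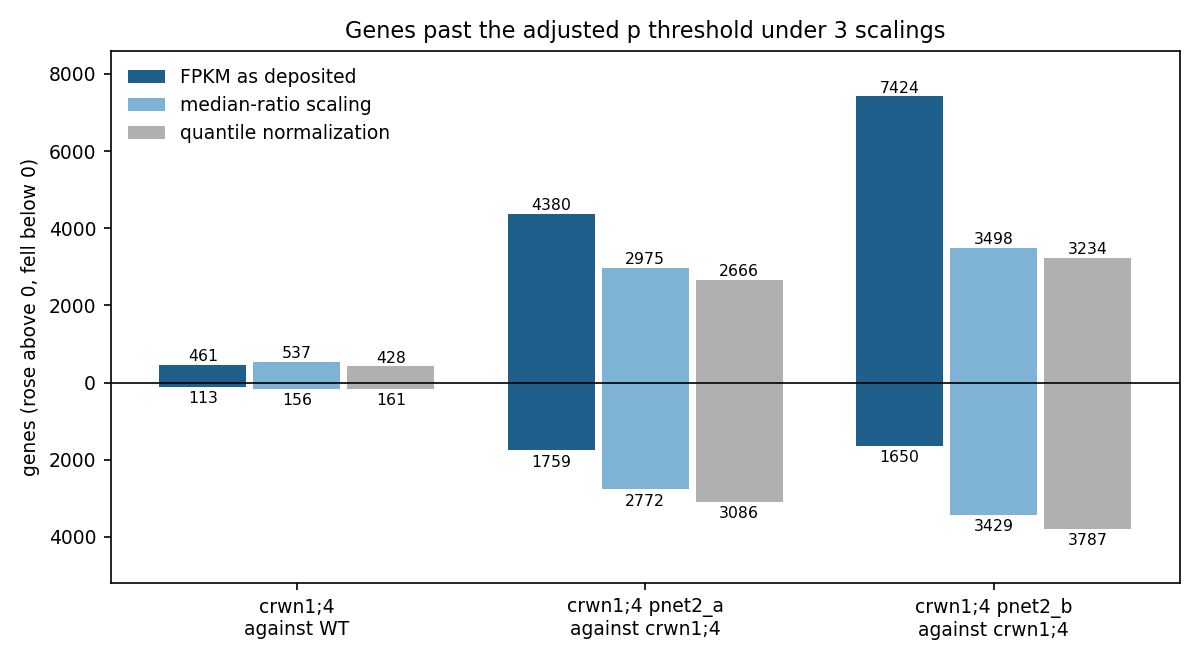
Number of genes that rose and fell past the threshold in the double mutant against WT and in each triple mutant against the double mutant, with the FPKM as deposited, after median-ratio scaling and after quantile normalization. In the pnet2_b triple mutant the rises go from 7424 to 3498 and 3234, and the falls from 1650 to 3429 and 3787.

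All 17 pathogenesis-related genes rose (median relative to all genes 1.97, adjusted p = 2.2e-09, adjusted p = 0.147 with an estimated correlation), and so did all 18 salicylic acid genes (median 1.66, adjusted p = 8.64e-12, adjusted p = 0.108 with an estimated correlation). WRKY70 had 145.3 ± 11.7 against 34.2 ± 8.50 FPKM, NIMIN1, a partner of the salicylic acid receptor NPR1, 38.4 ± 1.89 against 3.5 ± 1.22, and PBS3, of salicylic acid synthesis, 20.7 ± 2.25 against 3.74 ± 0.477. All 9 camalexin genes rose (adjusted p = 2.21e-05, adjusted p = 0.108 with an estimated correlation). Of 20 NLR receptors 17 rose, or 18 adjusted over the list alone (adjusted p = 4.98e-06, adjusted p = 0.192 with an estimated correlation), and of 14 genes of pattern-triggered immunity 11 rose, or 12 adjusted over the list alone (adjusted p = 0.0025, adjusted p = 0.115 with an estimated correlation). All 14 endoplasmic reticulum folding genes rose (median 1.02, adjusted p = 4.46e-10, adjusted p = 0.154 with an estimated correlation), with BIP2 at 142.3 ± 13.5 against 51.4 ± 4.66 FPKM and CNX1 at 132.6 ± 15.6 against 59.0 ± 3.3. Of 15 DNA damage genes 13 rose (adjusted p = 0.000958, adjusted p = 0.183 with an estimated correlation), such as XRI1 (15.2 ± 1.54 against 4.27 ± 0.606 FPKM) and PARP2 (10.5 ± 1.11 against 2.66 ± 0.419). Senescence (15 of 17 rose, 1 fell), indole glucosinolate (9 of 11 rose, 1 fell), evening clock (8 of 9 rose, or 9 adjusted over the list alone) and iron lists (7 of 8 rose) were called upward with adjusted p = 0.000389, 0.0101, 0.00407 and 0.035. With an estimated correlation their adjusted p were 0.183, 0.218, 0.325 and 0.294, and the iron call ended without replicate 1 of this triple mutant (adjusted p = 0.0526) and with a filter of 5 FPKM (0.0895).

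All 22 photosystem subunits fell, with a median of -0.88 relative to all genes, and this call was kept with an estimated correlation (adjusted p = 4.33e-35, adjusted p = 0.0321 with an estimated correlation). All 18 antenna genes fell (median -1.0, adjusted p = 1.97e-31, adjusted p = 0.089 with an estimated correlation). Under quantile normalization the antenna list kept its call (adjusted p = 0.00676) with a median log2 change of -0.06 and 7 members falling, and the photosystem list had a median of -0.18 with 12 members falling. LHCB4.2 had 980.3 ± 44.6 against 1877 ± 71.2 FPKM, PSAD2 689.3 ± 18.6 against 1267 ± 5.72 and PSBQ2 1389 ± 19.8 against 2438 ± 63.6. Of 14 chlorophyll synthesis genes 11 fell, or 12 adjusted over the list alone (adjusted p = 3.02e-13, adjusted p = 0.108 with an estimated correlation), among them CHLM (187.2 ± 5.82 against 274.5 ± 8.16 FPKM). Of 16 carbon fixation genes 12 fell (adjusted p = 3.26e-14, adjusted p = 0.146 with an estimated correlation), a call that ended under quantile normalization (0.234). Of 13 cold genes 7 fell and 2 rose, of 11 cell expansion genes 5 fell and 2 rose, of 12 abscisic acid genes 2 fell and 2 rose, of 11 morning clock genes 5 fell and 3 rose, and of 13 guard cell markers 2 fell and 1 rose. These lists were called downward with adjusted p = 0.000607, 0.00012, 0.0154, 0.0113 and 0.0209, and with an estimated correlation adjusted p = 0.152, 0.179, 0.361, 0.115 and 0.265. EXPA8 had 24.6 ± 3.57 against 67.3 ± 3.54 FPKM. The median log2 change of the morning clock genes was -0.13 and their mean 0.01, so median and mean differed in sign. Quantile normalization ended the abscisic acid (0.0535) and morning clock (0.0517) calls, and median-ratio scaling the guard cell call (0.0689). The guard cell call also ended with a filter of 5 FPKM (0.17) and the abscisic acid call with no filter (0.058), and fry called neither of these lists (0.395 and 0.372) nor the cold list (0.0596).

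Several lists that were not called held rises, where the median of all genes was 0.23: cell cycle (12 of 21 rose, or 13 adjusted over the list alone, adjusted p = 0.0996), nuclear lamina and envelope (10 of 21 rose, 0.664), aliphatic glucosinolates (9 of 18 rose, 0.174), jasmonate (12 rose and 2 fell of 21, or 13 and 2 adjusted over the list alone, 0.0576), heat shock (6 of 12 rose, 0.386), oxidative stress (6 of 10 rose, with 1 fall adjusted over the list alone, 0.156) and DNA methylation (5 of 11 rose, or 6 adjusted over the list alone, 0.568). The other lists had adjusted p of 0.382 for jasmonate-ethylene defence (1 rose and 1 fell of 6, or 1 rise adjusted over the list alone), 0.828 for ethylene (3 rose and 1 fell of 5), 0.145 for auxin (3 rose and 3 fell of 9, or 3 and 4 adjusted over the list alone), 0.0754 for energy starvation (1 rose and 1 fell of 12), 0.463 for copper (4 rose and 1 fell of 10), 0.965 for phosphate (4 rose of 10), 0.458 for flavonoids (3 rose and 1 fell of 14), 0.977 for flowering time (2 rose of 9), 0.751 for vascular markers (3 rose of 12) and 0.12 for epidermis markers (none of 8 by limma, 1 fell at an unadjusted p below 0.05). Jasmonate was called upward with no filter (adjusted p = 0.0244), median-ratio scaling (0.0326) and quantile normalization (0.0145), and without WT replicate 2 (0.0483), double mutant replicate 2 (0.0162), replicate 2 of this triple mutant (0.0171) or replicate 3 of the pnet2_a triple mutant (0.0485). Aliphatic glucosinolates were called upward without double mutant replicate 2 (0.000872) and oxidative stress under quantile normalization (0.00731). Energy starvation was called downward under quantile normalization (0.0434) and without double mutant replicate 2 (0.0196) or replicate 2 of this triple mutant (0.0419). Fry called jasmonate (0.000434), heat shock (0.000104), oxidative stress (1.57e-06), phosphate (0.00379), aliphatic glucosinolates (0.024), cell cycle (0.00135), the nuclear lamina and envelope (0.00341), DNA methylation (0.000109) and flowering time (0.0109) upward. Of the 148 genes named by rule, 9 lost their call when some library was left out. Another scaling ended the call of 32, with 28 lost under quantile normalization and 20 under median-ratio scaling.

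The comparisons of the triple mutants with WT set the lines that combine crwn1;4 with an added mutation against WT. In the pnet2_a triple mutant 6856 genes changed (4845 rose, 2011 fell) and in the pnet2_b triple mutant 9108 (7341 rose, 1767 fell). Median-ratio scaling gave 3591 rises and 3104 falls in the first and 3878 and 3612 in the second, and quantile normalization 3046 and 3659 and 3467 and 4311. The log2 change of PR1 was 7.49 (SE 0.453, adjusted p = 1.82e-08) and 7.60 (adjusted p = 1.01e-08), and that of PR2 5.63 and 6.07. Of the 17 pathogenesis-related genes 17 rose in each, of the 20 NLR receptors 18 and 20, and of the 14 folding genes 14 in each. All 22 photosystem subunits fell in each, and 16 and 18 of 18 antenna genes, where quantile normalization left 8 and 16 photosystem and 2 and 7 antenna genes falling. In the pnet2_b triple mutant the photosystem call was kept with an estimated correlation (adjusted p = 0.0323), while no list was called so in the pnet2_a triple mutant, where the smallest adjusted p was 0.073 with an estimated correlation. Guard cell markers were called downward in both, with 6 and 7 of 13 members falling (adjusted p = 2.09e-05 and 3.04e-05, adjusted p = 0.108 and 0.109 with an estimated correlation). Quantile normalization ended the antenna call in the pnet2_a triple mutant (adjusted p = 0.621) and the carbon fixation calls in both (0.934 and 0.633). The cold and abscisic acid lists had been called upward in the double mutant with 4 of 13 and 4 of 12 members rising, calls that were lost with an estimated correlation (adjusted p = 0.073 and 0.112 with an estimated correlation). Camera called neither in either triple mutant against WT (adjusted p = 0.977 and 0.351 with pnet2_a, 0.605 and 0.611 with pnet2_b), while fry, which does not set a list against other genes, called both upward (0.00684 and 0.0159 with pnet2_a, 0.00214 and 0.00549 with pnet2_b). The median log2 change of all genes against WT was 0.09 with pnet2_a and 0.212 with pnet2_b. Fry does not take this shift off, so its calls do not set these lists apart from other genes.

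The genes changed in the double mutant were followed into the triple mutants with each double mutant library held out in turn. Genes called as rising without that library (401, 411 and 239 genes) had a median log2 change of 1.03 ± 0.155 further in the pnet2_a and 1.27 ± 0.168 in the pnet2_b triple mutant, against 0.11 and 0.23 for all genes (mean ± SD over the 3 libraries held out). Of these genes 78.7 to 87.3% and 85.4 to 91.8% were higher still. The share of all genes that were higher was not counted, and the medians of all genes were positive too. Genes called as falling (44, 130 and 66) had median changes of 0.15 ± 0.064 and 0.25 ± 0.085, which lie near the medians of all genes. Of the genes called as falling, 25 to 46.2% were lower still with pnet2_a and 19.7 to 37.7% with pnet2_b.

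The triple mutants were similar to each other in their changes from the double mutant. Across genes, the correlation of their log2 changes was 0.893 and the covariance 0.205. Unchanged genotypes simulated against shared controls gave a correlation of 0.502 and a covariance of 0.0118, so the covariance lay 0.193 above that of the simulation. Genes that rose in both numbered 4169 where independent lists of that size share 1702, and genes that fell in both 1190 where these share 152. Opposite calls were made for 13 genes. After median-ratio scaling 2512 rose in both, 2253 fell in both and 5 were called in opposite directions. The simulated value leaves out real effects and the independent value leaves out the shared controls, and 3 control libraries cannot give each triple mutant 2 of its own, so part of the excess in shared genes may come from them. With 1 double mutant library as control of one triple mutant and the remaining 2 of the other, chosen after the data were seen, the covariance was 0.176 to 0.1999 over the 6 assignments and the correlation 0.7512 to 0.7895.

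The direct comparison of the pnet2_b with the pnet2_a triple mutant gave 550 genes, 406 higher and 144 lower with pnet2_b. Photosynthesis transcripts were lower with pnet2_b: all 18 antenna genes and 20 of 22 photosystem subunits fell, at list medians of -0.39 and -0.31, and both calls were kept with an estimated correlation (adjusted p = 0.0423 and 0.0241). Under quantile normalization both lists stayed called, with 6 and 2 members falling. The flowering repressor gene MAF5 had 13.3 ± 1.65 FPKM with pnet2_b and 1.71 ± 0.581 with pnet2_a (mean ± SD, n = 3; log2 change 2.42, SE 0.222, adjusted p = 0.000118). VSP1 had 2.81 ± 0.999 FPKM with pnet2_a and a mean of 29.8 with pnet2_b (log2 change 2.86, SE 0.364, adjusted p = 0.00119). The locus AT3G01345 was listed at 0 in every library but those of the pnet2_a triple mutant, where it had 145.9, 130.5 and 131.1 FPKM. The number of genes depended on the settings. Median-ratio scaling gave 520, with 132 rises and 388 falls and 276 genes shared with the 550. Quantile normalization gave 167 rises and 225 falls. Leaving out 1 library gave 208, 113 and 199 without replicates 1, 2 and 3 of the pnet2_a and 224, 179 and 151 without those of the pnet2_b triple mutant.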

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

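The tests of explanations given here, including the counts of splits, were written down only after the results they bear on had been seen, whereas the comparison of the triple mutants with each other was planned. That comparison, limma on the difference between the pnet2_b and the pnet2_a triple mutant, gave 550 genes past the threshold, and 55 of the genes named for the first 3 comparisons were among genes that differed so. By log2 change, AT2G09785 (3.00, 212.6 ± 11.7 against 25.7 ± 1.58 FPKM, mean ± SD, n = 3), VSP1 (2.86) and MAF5 (2.42) were higher with pnet2_b, and LSU1 (-1.22) and AT4G22485 (-1.95) were lower. These differences do not tell which triple mutant departed from the double mutant. LSU1 had 12.69 to 14.73 FPKM with pnet2_a, 4.6 to 5.8 with pnet2_b and 0.62 to 2.45 in the double mutant libraries. AT4G22485 had 24.41 to 50.89, 4.8 to 11.25 and 2.54 to 4.74 FPKM in the same order. The LSU1 call (adjusted p = 0.0309) ended without any one of the 6 libraries compared, at adjusted p of 0.0756 to 0.107, and was 0.000801 to 0.126 over all alternatives. AT3G01345 had a fitted change of -7.09, which is no bound since it was listed at 0 in every pnet2_b library. AT2G09785 overlaps AT2G47110 and AT4G22485 overlaps AT4G22475, and the strand setting is unknown. The values of AT2G09785 and AT4G22485 may thus hold reads of the overlapping genes.

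Among the gene lists, where the median of all genes was 0.12, camera called these median log2 changes upward with pnet2_b: 0.387 for salicylic acid synthesis and signalling (adjusted p = 0.00149, adjusted p = 0.336 with an estimated correlation), 0.353 for endoplasmic reticulum folding (4.02e-08, 0.196), 0.383 for aliphatic glucosinolates (1.88e-07, 0.231), 0.482 for flowering time (0.00168, 0.146), 0.279 for epidermis markers (0.0122, 0.152), 0.247 for energy starvation (0.00694, 0.247) and 0.166 for NLR receptors (0.0209, 0.482). Called downward were the antenna at -0.394, photosystem subunits at -0.314 and phosphate starvation at -0.221, all kept with an estimated correlation (adjusted p = 0.0423, 0.0241 and 0.0423). Also called downward were carbon fixation at -0.178 (adjusted p = 0.109 with an estimated correlation), chlorophyll synthesis at -0.092 (0.149), jasmonate-ethylene defence at -0.216 (0.224) and copper at -0.017 (0.14). The NLR call ended under median-ratio scaling (adjusted p = 0.128), quantile normalization (0.0647), without replicate 1 of the pnet2_a triple mutant (0.0638) and without replicate 3 of the pnet2_b triple mutant (0.124). The copper call ended without replicate 2 of the pnet2_a triple mutant (0.0737), with no filter (0.0558) and under quantile normalization (0.0693). Fry called neither the copper (0.467) nor the jasmonate-ethylene list (0.377). Lists not called here were called under other settings. Vascular markers were called upward with no filter (0.0469), median-ratio scaling (0.0218), quantile normalization (0.0305) and without replicate 3 of the pnet2_b triple mutant (0.0267), and DNA methylation upward with no filter (0.0454), median-ratio scaling (0.0381), limma without trend (0.0258) and without replicate 3 of the pnet2_a triple mutant (0.035). The pathogenesis-related list was called upward under quantile normalization (0.0218), in the fit on these 2 genotypes (0.0117) and without double mutant replicate 3 (0.0344), and DNA damage upward with a filter of 5 FPKM (0.0256) and median-ratio scaling (0.0325). Oxidative stress was called upward under quantile normalization (0.025), camalexin upward in the fit on these 2 genotypes (0.0461), heat shock downward with no filter (0.0116) and iron downward without replicate 2 of the pnet2_a triple mutant (0.0395). Fry also called camalexin (0.0352), pattern-triggered immunity (0.00137), ethylene (0.038), auxin (0.0344), senescence (0.0488), oxidative stress (0.00552), morning clock (0.00229), DNA damage (0.0177), nuclear lamina and envelope (0.0372) and DNA methylation (0.0011) upward.

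The first pattern is the excess of rises over falls in the triple mutants. If it came from the fixed total of the FPKM alone, median-ratio scaling would even it out, but among changes of at least 2-fold 4.24 rises per fall remained in the pnet2_a and 3.65 in the pnet2_b triple mutant, which argues against a fixed total as the whole cause for that part. For smaller changes it stays open: the share lost by the 100 most abundant WT genes would raise all other genes by a log2 of 0.132 in the pnet2_a and 0.235 in the pnet2_b triple mutant, beside medians of all genes of 0.11 and 0.23. No added standard gives absolute amounts, so a fixed total and a general rise cannot be told apart for these small changes. An effect of the added mutations on transcription at large is a biological explanation that was not tested.

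The second pattern is that replicate 3 of the double mutant lay toward the triple mutants. RNA of the pnet2_a libraries in it would need a share of 14.1% (13.2 to 15.3%, 794 genes), which would put AT3G01345 at 19.2 FPKM, but it was listed at 0 where the smallest value above 0 was 0.293, so this source is excluded. RNA of the pnet2_b libraries stays open: the 12 genes higher with pnet2_b gave a median share of 5.9% (0.2 to 11.2%), against a needed 11.5% (10.7 to 12.4%), and these ranges overlap. The ranges come from 2000 bootstrap resamples over genes, which treat genes of 1 library as independent and so are too narrow. The 794 genes were also chosen against the other double mutant libraries, which by itself can raise the share in replicate 3. A stronger defence state of the plants behind replicate 3 is also open and was not tested.

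The third pattern is a set of 6 loci listed at 0 in some genotypes and at 3 FPKM or more in every library of others. MRD1 (AT1G53480) and AT1G07887, which overlap each other, were at 0 in WT and at 14.8 to 27.3 FPKM in the mutants, AT1G64795 was above 0 in the double mutant alone (20.9, 26.8 and 32.1), AT2G05695 in WT alone (6.82, 8.77 and 8.32) and AT3G01345 in the pnet2_a triple mutant alone, while AT2G18193 was at 0 in WT alone. An exchange of a pair of libraries between genotypes is excluded by a wider set of 129 loci, set apart by at least 2 of the 3 libraries of a genotype: in none of 54 pairs did both libraries have the other genotype's state at more than 20% of their loci (5 to 115 loci a pair), where an exchange needs nearly all. A fixed share of the reads of AT1G64790, which overlaps AT1G64795 on the other strand, is excluded, as it would put AT1G64795 at 23.4 FPKM or more in each of the other 9 libraries, where it was at 0. A share taken in the double mutant alone stays open, since it would change AT1G64790 by a log2 of only -0.071 beside a measured 0.078 (SE 0.089), and so do a sequence or strain difference carried by a whole line and an effect of the mutations, which were not tested.

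Each comparison of 3 with 3 libraries allows 10 splits, too few for a share under 0.05. In each comparison 1 split, the real one, gave as many genes: 574 for crwn1;4 against WT, 6139 and 9074 for the pnet2_a and pnet2_b triple mutants against it, 6856 and 9108 for these against WT, and 550 between them. The highest of the other splits gave 2, 0, 0, 0, 1 and 1 genes. Each of these splits mixes both genotypes in each group, so the real difference enters the spread. Low counts there follow from the design and lend no support to the real split.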

How the results depend on the processing

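The alternatives were planned, except for separate control libraries for each triple mutant, chosen only after the result was seen. Of 372 named results past the threshold, 268 were called in all of the 23 alternatives that apply to a single result and kept the gene, and 104 lost the call in at least 1. Of these, 1 changed direction, SQD1 in the pnet2_b triple mutant (0.23, and -0.019 under median-ratio scaling, which takes off the median of all genes). Under quantile normalization LHCB1.2 with pnet2_a (-0.52) and RBCS3B in both triple mutants (-0.23 and -0.53) had a change of 0, since they rank highest in every library and are tied by construction.

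The fit on the 2 genotypes compared called 29 genes in crwn1;4 against WT and 908 between the triple mutants, where limma without trend called 201 and array weights 1150. The cause was not tested, except that the first has fewer residual degrees of freedom. With a 2-fold minimum the 6 comparisons gave 117, 939, 1232, 1284, 1536 and 43 genes (crwn1;4 against WT, each triple mutant against it with pnet2_a first, each against WT, and pnet2_b against pnet2_a). In the same order, camera called 19, 25, 20, 22, 18 and 14 lists with the preset and 1, 0, 1, 0, 1 and 3 with an estimated inter-gene correlation, and fry, which tests each list on its own, called 15, 29, 26, 24, 29 and 22. The further change of the genes raised in the double mutant was 0.809 with pnet2_a and 1.05 with pnet2_b when all 3 crwn1;4 libraries served for call and measurement, and for the genes lowered 0.274 and 0.383. Using the same libraries for both pulls these 4 values toward the reverse of the call. With each library held out in turn and a 2-fold minimum it was 1.797 and 2.237 for the genes raised and 0.055 and 0.05 for those lowered, where fewer genes are left.

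Leaving out 1 library in turn gave 301 to 689, 4726 to 6334, 7536 to 9261, 5683 to 6834, 7804 to 9061 and 113 to 648 genes, 18 to 21, 22 to 27, 19 to 23, 22 to 23, 17 to 18 and 13 to 15 lists, and a correlation between the triple mutants of 0.8796 to 0.9057. With separate crwn1;4 libraries for each triple mutant that correlation averaged 0.772, where the shared controls no longer add to it and fewer libraries stand behind each change. With the replicate number as a block the counts were 562, 6046, 9019, 6759, 9042 and 403. None of 18 same-numbered pairs correlated above 0.1 in their deviations from the genotype means (-0.084 to 0.068), so no strong pairing by number showed. A weak pairing cannot be told from none by these values, and the labels do not settle it. The block, like other settings, also called aliphatic glucosinolates downward with pnet2_a (adjusted p = 0.0489) and vascular markers upward in pnet2_b against pnet2_a (0.045). The read depth is unknown, so what depth limits could not be stated.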

Other observations

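The gene families described here and the tests of gene position were chosen only after the data had been seen. Families were taken from symbols with a shared stem and at least 10 members kept (112 families), and none was called with an estimated correlation in any comparison. A stem can join genes of different kinds, so a family name need not describe every member. With the preset, 13 families were called in the double mutant against WT, 9 of them upward, 24 in the pnet2_a triple mutant against the double mutant (12 upward) and 21 in the pnet2_b triple mutant (9 upward), and only some are described. Of 45 WRKY transcription factors, 10 of which are in the lists above, 6 rose in the double mutant, 30 with pnet2_a and 33 with pnet2_b, at medians relative to all genes of 0.27, 0.58 and 0.70 (camera adjusted p = 0.000174, 3.09e-08 and 3.59e-07, with adjusted p = 0.561, 0.281 and 0.292 with an estimated correlation). Of 37 NAC transcription factors 5, 26 and 27 rose (adjusted p = 0.00365, 1.5e-05 and 0.000165). Of 35 cysteine-rich receptor-like kinases (CRK), none of them in the lists, 8, 22 and 25 rose and 0, 2 and 2 fell, and of 39 receptor-like proteins (RLP) 5, 22 and 26 rose and 0, 1 and 1 fell. Both were called upward (CRK adjusted p = 2.75e-08, 0.000332 and 0.00207, RLP adjusted p = 0.00435, 8.1e-05 and 0.000165). With an estimated correlation the adjusted p of the NAC, CRK and RLP families were 0.454 to 0.628. Of 20 ERF genes 3 rose in the double mutant, where the family was called upward (adjusted p = 0.00365, adjusted p = 0.292 with an estimated correlation), and 12 and 13 rose with 1 and 0 falls in the triple mutants, where it was not called (adjusted p = 0.0584 and 0.146). Of 17 IAA regulators of auxin response, 6 of which are in the lists above, 0 and 3 rose and 10 and 5 fell in the triple mutants, and the family was called downward (medians relative to all genes -0.54 and -0.40, adjusted p = 0.00022 and 0.0222, with adjusted p = 0.561 and 0.642 with an estimated correlation).

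Among families called downward in the triple mutants, 10 of 12 HCF genes, many of which serve the assembly of photosynthetic complexes, fell in each triple mutant, at medians of -0.40 and -0.55 relative to all genes (adjusted p = 9.96e-07 and 5.93e-09, with adjusted p = 0.137 and 0.105 with an estimated correlation). Of 13 fasciclin-like arabinogalactan proteins (FLA) 7 and 5 fell, and of 15 KCS enzymes of wax and fatty acid elongation 9 and 4 fell with 1 rise with pnet2_b. Of 18 genes with the symbol stem PIP, which holds aquaporins but may also hold other genes, 10 and 8 fell while 1 and 2 rose. These families had adjusted p of 6.69e-06, 9.08e-05 and 0.000138 with pnet2_a and 0.000474, 0.00233 and 0.000172 with pnet2_b, and adjusted p = 0.561 to 0.642 with an estimated correlation. Of 22 RPL ribosomal proteins none passed in the double mutant, although the family was called downward (median -0.15, adjusted p = 7.79e-05, adjusted p = 0.595 with an estimated correlation). The medians of the families named here kept their direction under median-ratio scaling, TPM and quantile normalization.

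Since lamina proteins tether chromatin, one hypothesis was that genes in gene-poor parts of the chromosomes rose more often. Of 1584 genes within 3 Mb of the gene-poorest 1-Mb window of each chromosome, 1.01% rose at least 2-fold in the double mutant, against 0.52% of 17431 genes elsewhere (difference 0.49 points, two-sided permutation p = 0.0377, adjusted 0.113). With pnet2_a the shares were 5.43 and 4.2% (difference 1.23 points, permutation p = 0.151, adjusted 0.226), and with pnet2_b 6.69 and 5.9% (0.79 points, permutation p = 0.39, adjusted 0.39). None passed the correction, so the hypothesis is left undecided.

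A further hypothesis was that neighbouring genes rose together. Neighbours were genes next to each other among the genes kept, so genes that were not kept may lie between them. Pairs of neighbours of different families that do not overlap, and that both rose at least 2-fold, numbered 58 with pnet2_a, against a mean of 28.3 and a highest of 48 over 10000 permutations, and 90 with pnet2_b, against 54.3 and 85 (one-sided permutation p = 1e-04 for each, the smallest these can give, adjusted 0.00015). In the double mutant 1 such pair was found, against a mean of 0.5 and a highest of 5 (permutation p = 0.378). Pairs of the same family (3 in the double mutant, 51 with pnet2_a and 66 with pnet2_b) and overlapping pairs (2, 28 and 46) were left out, the overlapping ones after a first count had been seen. A family was told by a shared symbol stem or the same product name, so related neighbours named differently stayed in. Regional control of expression is a candidate explanation for the 58 and 90 pairs, but reads running from a gene into its neighbour may give the same and were not tested. Related neighbours that were named differently may also give it, and this was not tested either.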
